A study of Halobacterium salinarum NRC-1 with 8 samples.

How the data were processed

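The series measured transcript levels in Halobacterium salinarum NRC-1, a salt-loving archaeon, with ura3 and boa4 deleted. Per the labels, cells grew in rich medium to mid-log phase as 50 mL cultures in 125 mL flasks, shaken at 210 rpm (high oxygen) or 100 rpm (low oxygen), in light or in the dark. There was 1 culture for each of the 4 combinations. Each culture's RNA was hybridised on 2 two-colour arrays, against an NRC-1 mid-log standard reference, with the dyes exchanged between the arrays. On replicate 1 of each culture the culture's RNA carried Alexa 532 and on replicate 2 it carried Alexa 647.

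Per the file headers, the scanner tables give for each spot a mean foreground intensity, a median background intensity and a peak intensity, for each dye at a high and a low scanner setting. They also hold a spot confidence as a percent, per the file headers, which was read and not used as a filter. Nothing was subtracted or normalized in these intensities, per the file headers, and the image software is not given in the sources used here. The authors' value table holds log10 ratios. In bright unsaturated spots, from 374 to 1355 per array, it followed the log10 of Alexa 532 over Alexa 647 foreground at the high setting, without background subtraction, with a shift per array and without turning the exchanged dyes. There the correlation ran from 0.9996 to 1.000 and the slope was 1.000 on 7 arrays and 0.989 on high-oxygen dark replicate 2. Over all spots its correlation with the scanner ratios ran from 0.765 to 0.935 per array when spots were ordered by print layout, against 0.106 to 0.273 when ordered by the scanner's own spot number. How its dim and saturated spots were made is not given in the sources used here. The medians of its columns were 0.0353, 0.0457, 0.0673, 0.0337, 0.0265, 0.0599, 0.0560 and 0.0649, in the order high-oxygen light, high-oxygen dark, low-oxygen light and low-oxygen dark, replicate 1 before replicate 2. The purpose of its shift stays unknown. From 0 to 1095 of its spots per array hold an exact 0, which was treated as missing.

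The print layout holds 10752 spots, 4 for each of 2688 probes. Intensities of adjacent spots of one probe correlated with r = 0.994, against 0.136 for adjacent spots of different probes. The annotation of the platform named 1 gene for 133 of these probes, none had several, and 2555 were unnamed here. Unnamed probes are written with the number of their first spot. boa4 was not among the names, and pyrF was taken as ura3. Control spots are not marked in the tables used here, so any on the array stayed in. Spot flags and scan dates are likewise not in these tables. The sample titles number the arrays consecutively, with all high-oxygen arrays before all low-oxygen arrays, so oxygen cannot be told apart from array order. All 133 names were found in a gene table of strain 91-R6 (assembly ASM479960v1), which was used only to see which genes neighbour each other, since the array's genome build is not given in the sources used here.

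The high scan was used, and a spot with any saturated pixel (peak of 65535) took its low-scan value, brought to the high scale by a robust line fitted per array and dye to unsaturated spots above 500 in the low scan (MASS 7.3.60.0.1). Background was corrected with normexp and an offset of 50, and each array was normalized by global loess, which removes a trend of the ratio with intensity (limma 3.58.1, R 4.3.3). Every log2 ratio was turned to culture over reference by the dyes in the labels, the 4 spots of a probe were averaged, and the 2 arrays of a culture were averaged to 1 replicate. A probe was called well above background on an array where its mean foreground in the culture's dye exceeded 2 times its local background. A probe that met this on no array of one side is given no fold for oxygen or light, where brightness differs between arrays. Against the reference, measured on the same array, it is given only a bound: the brighter side's mean against the higher of the dimmer side's own signal and the lowest signal among probes well above background on that array, per dye after loess and Aquantile. No fold is given where both sides were that dim.

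One limma model with additive oxygen and illumination terms was fitted to the 4 culture means, with 2 cultures on each side of each comparison. It leaves 1 residual degree of freedom, to which the empirical Bayes prior added 3.12. Its intercept tested the mean of the cultures against the reference and leaves out the reference's own spread. An interaction of oxygen and light is this model's residual and could not be tested on cultures. Tests were two-sided, with Benjamini-Hochberg adjustment over the 2688 probes and an adjusted p under 0.05 as the threshold. Errors after ± are standard errors from this fit, n = 4 cultures. Where the 525 probes well above background on all 8 arrays were tested alone, errors are from that refit of the same 4 cultures. The same value can therefore carry 2 different errors. Members of a gene list were counted by named probe, whether or not they were well above background, so some directions in lists rest on dim probes. Lists of at least 3 such members were tested with cameraPR at a preset correlation of 0.01, adjusted over the lists of their kind. With 1 residual degree of freedom, the correlation estimated in its place is itself poorly known.

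Groups, model, 21 gene lists, the rule for named genes and most alternatives were set before the data were examined. The scan merging, the background criterion and 7 further lists (named as later lists) were set after the tables had been opened and before any contrast was computed. Values of pyrF, bat, hop, arcA, csg and sop2 had been seen by then in checks of the layout. Lists could be filled only by gene symbol, which left 7 of the 21 without a member. The rule named the deleted genes and, for oxygen and light, the 10 largest differences per direction. These had the same sign at both levels of the other factor and in both dye orientations, and genes past the threshold came first. Of all probes 36.7% met this sign condition for oxygen and 37.8% for light, against 33.35% in simulated noise. Meeting it is therefore little evidence of a response. The rule also took up to 4 members per list. Against the reference it took the 10 largest per side past the threshold with the same sign on all 8 arrays. It was applied to probes with a gene name, and a few unnamed probes are added.

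In 20 simulated data sets with the fitted spread, 200 of the 2688 probes were given an oxygen change. The model recovered 0.25% of changes of 0.5 on the log2 scale, 90.8% of changes of 1.00 and 98.9% of changes of 2.00, and at 1.00 false calls were 5.95% of all calls. With fewer changed probes the adjustment is stricter, so these shares hold only for 200 changed probes. In the real oxygen fit probe_3453, at -0.96 ± 0.13, had a limma adjusted p of 0.732. Alternatives covered background correction, normalization, dim probes, averaging of spots, the prior, the use of the dye flips, each array left out and the authors' values. The number of arrays limits the precision.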

Results

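Transcript levels in the Δura3 Δboa4 strain of Halobacterium salinarum NRC-1 were compared across oxygen supply and illumination. boa4 takes its name from the bacterio-opsin activator family, and ura3 is the orotidine phosphate decarboxylase gene pyrF of pyrimidine synthesis. The 8 arrays came from 4 cultures, 1 for each of high oxygen in light, high oxygen in the dark, low oxygen in light and low oxygen in the dark, each on 2 arrays with exchanged dyes. All values are log2 ratios of culture over a common NRC-1 reference RNA. Each oxygen or light level was represented by 2 cultures, so the tests rest on the spread between 4 cultures grown once.

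Of 2688 probes, 525 were well above background in the culture's dye on all 8 arrays and 1269 on none. Among the 133 genes with a name, 52 and 30 were in these classes. The share of probes well above background in the culture's dye differed between arrays and was higher on the low-oxygen arrays. It was 23.7% and 19.9% on the high-oxygen light arrays, 34.7% and 28.5% on the high-oxygen dark arrays, 47.1% and 48.9% on the low-oxygen light arrays, and 48.3% and 36.3% on the low-oxygen dark arrays. In the reference's dye, where every array held the same RNA, the shares in that order were 24.8% and 13.2%, 42.6% and 28.7%, 50.3% and 37.5%, and 58.3% and 31.8%. Within each dye orientation these were also higher on the low-oxygen arrays, so the shift was not particular to the cultures' RNA. On high-oxygen light replicate 2 the median background lay above the median foreground in both dyes. It was 2630 against 2035 in Alexa 532 and 3133.5 against 2934.6 in Alexa 647, the culture's dye there.

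The deletions could not be checked. The pyrF probe was not well above background on any array, in the culture's or in the reference's dye, so it has no fold. No probe is named boa4 in the annotation used here. The related activator gene bat, which controls bacterio-opsin, was also not well above background on any array.

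The first comparison asked which transcripts responded to oxygen. Among genes measured on both sides, folP of folate synthesis was 0.23 ± 0.13 higher at high than at low oxygen, the DNA gyrase subunit gene gyrA 0.22 ± 0.12 and the co-chaperone gene dnaJ 0.19 ± 0.10. The purine synthesis gene purD was 0.18 ± 0.11 and the cell surface glycoprotein gene csg 0.14 ± 0.10 on the same side. The heme synthesis gene hemA, at 0.14 ± 0.10, the aspartate carbamoyltransferase gene pyrB, at 0.12 ± 0.10, and the cobalamin gene cbiT, at 0.12 ± 0.10, completed the measurable higher side. On the lower side glmS of amino sugar synthesis was measured on both sides, at -0.22 ± 0.10. None of these passed the test, with limma adjusted p from 0.772 to 0.836. With the authors' values csg stood at -0.06, and pyrB was at -0.02 with print-tip loess.

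The genes hisG, mvk, serS, hop, cca and htr7, all with lower ratios at high oxygen, were well above background on low-oxygen arrays and on no high-oxygen array, so no fold is given. hisG of histidine synthesis and the mevalonate kinase gene mvk were well above background on 4 of 4 low-oxygen arrays. The seryl-tRNA synthetase gene serS and the tRNA nucleotidyltransferase gene cca were so on 3 of 4, and hop, which encodes the chloride pump halorhodopsin, and the transducer gene htr7 on 2 of 4. Their adjusted p ran from 0.732 to 0.789, and the low-oxygen arrays had more probes above background, as given above. The genes nadC, cysS, hutU, glyS and uvrA also met the rule and were not well above background on any array.

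No gene list passed for oxygen, and each of the 7 testable lists had an adjusted p of 0.908. Chemotaxis and Htr transducers, which steer swimming, held 9 named genes, 7 with higher and 2 with lower ratios at high oxygen (4 and 5 with print-tip loess and with the authors' values). Among them cheA was at 0.08 ± 0.10 and cheY at 0.03 ± 0.10. The counts include genes not well above background, such as htr7 on the high-oxygen arrays. Rhodopsins and their transducers held 3 of 5 higher, with sop2 at 0.11 ± 0.11 and htr1 at -0.15 ± 0.10, and the list's median of 0.05 and mean of -0.03 differed in sign. The TCA cycle list held 3 of 4 higher (1 of 4 with median centring and with the authors' values), with sucC at 0.02 ± 0.11 and sucD at -0.04 ± 0.10. Cobalamin synthesis held 3 of 4 higher (1 of 4 with the authors' values), with cbiT as above and cobN at -0.12 ± 0.10. Heat shock and proteasome genes held 4 of 5 higher (2 of 5 with median centring, 1 of 5 with the authors' values), with dnaK at 0.07 ± 0.10. Pyrimidine synthesis held 2 of 3 higher (1 of 3 with the authors' values), pyrB and pyrI, the latter at 0.11 ± 0.10. DNA repair held 1 of 3 higher (2 of 3 with print-tip loess and without background correction), uvrB at 0.15 ± 0.14. These counts include pyrF, taken as the deleted ura3, and uvrA, both not well above background on any array.

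Some lists had too few named genes for a test. Both measured genes of arginine fermentation were close to 0 for oxygen, arcA at 0.02 ± 0.10 and arcC at 0.00 ± 0.11. The ribosomal protein gene rpl12p stood at 0.09 ± 0.10, the phosphate regulator gene phoU at -0.16 ± 0.10, the respiratory genes sdhC at -0.07 ± 0.10 and nuoL at -0.01 ± 0.10, and the oxidative stress gene dpsA at 0.10 ± 0.10. Under 1 or more of the other scalings the values of cheY, sucC, dnaK, pyrI, arcC, nuoL, rpl12p (-0.06 from the high scan alone) and dpsA (-0.05 with the authors' values) had the opposite sign. Purple membrane synthesis and the bacterio-opsin activators held bat alone. Gas vesicles, DMSO and TMAO respiration, terminal oxidases and halocyanins, ATP synthase, flagella, the transcription factors TBP and TFB, and transposases had no named probe.

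Over all probes 0 passed an adjusted p under 0.05 in limma for oxygen, and the lowest adjusted p was 0.732. At an unadjusted p under 0.05 there were 176 probes, against 134.4 by chance. With a robust, intensity-trended prior 29 unnamed probes passed, with median centring in place of loess 29, and with the authors' values 37, all without a gene name. Among the 525 probes well above background on all 8 arrays, a set chosen after the data were seen, 2 passed. They were probe_2115, higher by 0.57 ± 0.05, and probe_3453, lower at -0.96 ± 0.09, both with limma adjusted p of 0.0395 and both singled out after their values were seen.

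The second comparison asked which transcripts responded to light. folP was 0.44 ± 0.13 higher in light than in the dark, and the purine synthesis genes purF and guaB were 0.32 ± 0.16 and 0.15 ± 0.10 higher. The transducer gene htr8 stood at 0.27 ± 0.11, the translation initiation factor gene infB at 0.26 ± 0.14 and sop2, which encodes the blue-light sensor sensory rhodopsin II, at 0.16 ± 0.11. With lower values in light were pan1, a proteasome-activating nucleotidase gene, at -0.45 ± 0.19, htr7 at -0.17 ± 0.10, hisG at -0.14 ± 0.11, the transducer gene htr1 at -0.11 ± 0.10 and the cobalamin gene cobN at -0.10 ± 0.10. None passed the test, with limma adjusted p from 0.619 to 0.822. The values of infB, pan1, hisG and htr7 rest in part on high-oxygen arrays, on none of which these genes were well above background, and htr7 was so on 1 array in light and 1 in the dark. htr8 and htr1 were well above background on 1 high-oxygen array. With the authors' values htr7 stood at 0.13 and hisG at 0.01, and htr1 was at 0.01 with print-tip loess.

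nadC, purB, truA, gatC, hutU, tmk, mamA and radB met the same rule with probes not well above background on any array. glpK was well above background on 1 array in light and on none in the dark, so no fold is given. No list passed for light, where the lowest adjusted p of the 7 lists was 0.958. Rhodopsins and their transducers held 3 of 5 genes higher in light (5 of 5 with print-tip loess, 4 of 5 with the authors' values), with sop1 at 0.09 ± 0.13 and htr2 at -0.07 ± 0.10. Chemotaxis and Htr transducers held 5 of 9 higher (8 of 9 with median centring), with cheA at 0.07 ± 0.10. TCA cycle genes held 2 of 4 higher (4 of 4 with median centring), with icd at -0.03 ± 0.10 and a median of -0.01 against a mean of 0.01. Heat shock and proteasome genes held 3 of 5 higher (2 of 5 with the authors' values), with dnaK at 0.08 ± 0.10 and a median of 0.01 against a mean of -0.08. Cobalamin synthesis held 1 of 4 higher (3 of 4 with median centring), with cbiT at -0.03 ± 0.10. Pyrimidine synthesis held 0 of 3 higher (2 of 3 with median centring), with pyrI at -0.05 ± 0.10, and DNA repair 3 of 3 (2 of 3 with median centring and with the authors' values). Their members pyrF, taken as the deleted ura3, and uvrA were not well above background on any array. Among lists without a test, arginine fermentation held arcC at -0.09 ± 0.11 and arcA at -0.07 ± 0.10 (0.03 with median centring). Under 1 or more of the other scalings the values of htr2, icd, cbiT and pyrI also had the opposite sign.

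Of 2688 probes 0 passed for light in limma. The lowest adjusted p was 0.619, and 207 probes had an unadjusted p under 0.05, against 134.4 by chance. With median centring in place of loess 107 probes passed, 10 higher and 97 lower in light, and with the authors' values 26. Only gatC and hutU of these have a gene name. Both were lower in light with median centring (adjusted p of 0.0273 and 0.0417) and not well above background on any array.

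**Figure D1:**
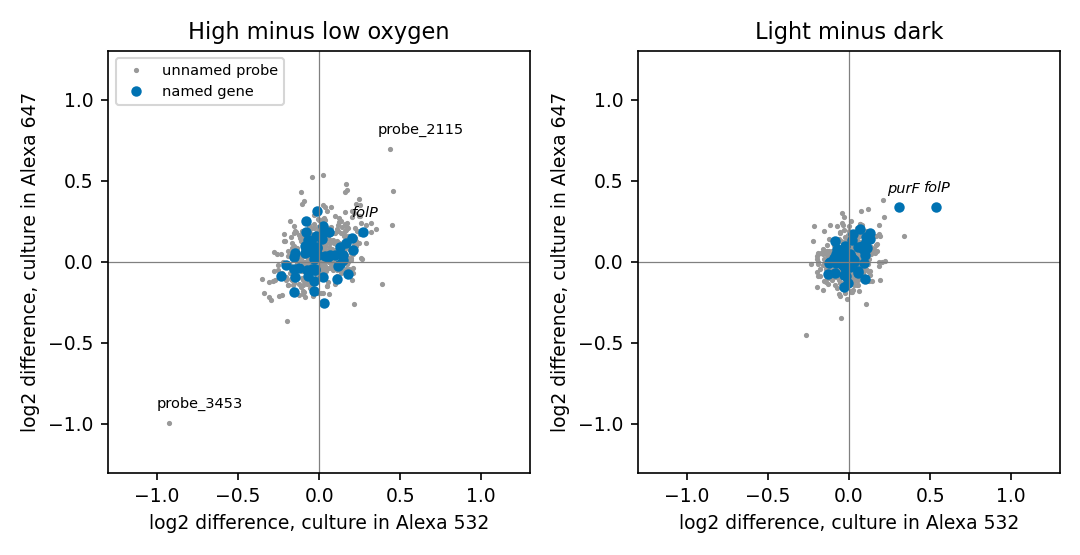
Log2 differences for the 525 probes well above background on all 8 arrays, high minus low oxygen (left) and light minus dark (right), from the arrays with the culture in Alexa 532 (x axis) against those with it in Alexa 647 (y axis), with blue points for named genes and grey for unnamed probes. Most points lie near 0, and r between orientations was 0.415 for oxygen and 0.261 for light. Labels mark probe_3453, probe_2115 and folP on the left and folP and purF on the right. On the left folP does not stand apart, since its 0.23 is exceeded by unlabelled probes such as probe_4747 at 0.45.

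The third comparison set the mean of the 4 cultures against the NRC-1 reference, which differs from them in strain and in growth, so these cannot be told apart. Among named genes, the carbamate kinase gene arcC, which serves arginine fermentation, was 1.37-fold higher in the cultures (log2 0.45 ± 0.05) and the argininosuccinate lyase gene argH 1.33-fold (0.41 ± 0.05). Lower were the ribosomal protein genes rpl12p at -0.73 ± 0.05 and rpmC, which encodes protein L29, at -0.51 ± 0.06, the only ribosomal protein genes with a name here. Also lower were the succinyl-CoA synthetase gene sucC at -0.35 ± 0.05, the carbamoyl phosphate synthase gene carB at -0.32 ± 0.05 and cbiT at -0.28 ± 0.05.

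Each of these 7 genes had the same sign on all 8 arrays, although carB was well above background in the cultures only at low oxygen, with limma adjusted p from 0.0409 to 0.0491. An eighth, the thiamine synthesis gene thiL, was not well above background in any culture and was at least 1.12-fold lower, with adjusted p of 0.0410. Of the other 3 named genes past the threshold, gyrA (-0.35 ± 0.06) and hemA (-0.39 ± 0.05) were lower on 7 of 8 arrays, and purB, higher on 6 of 8, was not well above background on any array in either dye. Sizes differed by dye. rpl12p was at -0.46 with the culture in Alexa 532 and -1.01 in Alexa 647, and argH at 0.17 and 0.64.

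**Figure D2:**
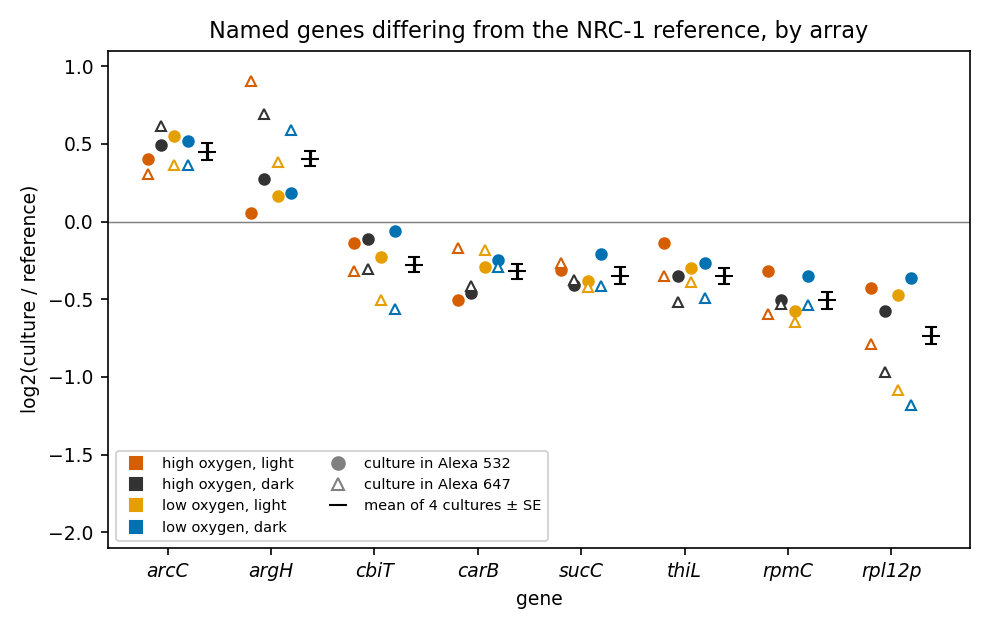
Log2 ratio of culture over reference (y axis) for the 8 named genes past the threshold with 1 sign on all arrays (x axis), with 1 point per array, colours for the 4 cultures, filled circles for the culture in Alexa 532, open triangles for Alexa 647, and black bars for the mean of the 4 cultures ± standard error. arcC and argH lie above 0 on every array and the other 6 genes below it, rpl12p and argH separate by dye, and the ratios of thiL come from cultures not well above background.

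In the TCA cycle list all 4 genes were lower than in the reference (3 of 4 from the high scan alone) and sucC passed, with citZ at -0.21 ± 0.05, sucD at -0.14 ± 0.05 and icd at -0.06 ± 0.05. The list itself had an adjusted p of 0.161, and an adjusted p of 0.700 with an estimated correlation. In chemotaxis and Htr transducers 8 of 9 were higher and none passed, with cheY at 0.18 ± 0.05 and cheB at 0.17 ± 0.05, and the list's adjusted p was 0.193. In rhodopsins and their transducers all 5 were higher (3 of 5 with print-tip loess) and none passed, with sop1 at 0.21 ± 0.06. Cobalamin synthesis held 3 of 4 lower (2 of 4 with print-tip loess), of which cbiT passed, and heat shock and proteasome genes 3 of 5 higher (2 of 5 with print-tip loess). DNA repair held 3 of 3 higher (2 of 3 with the authors' values) and pyrimidine synthesis 2 of 3, counts that include uvrA and pyrF, not well above background in the cultures. Of the 2 arginine fermentation genes arcC passed, and arcA stood at 0.25 ± 0.05 with adjusted p of 0.0548. Adjusted over the list alone, 2 genes passed in each of TCA cycle, cobalamin synthesis and arginine fermentation. There were 0 in rhodopsins, chemotaxis, DNA repair, heat shock and pyrimidine synthesis, and 0 in every list for oxygen and for light.

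Of 2688 probes 235 passed against the reference in limma, 120 higher and 115 lower, and 148 of them had the same sign on all 8 arrays. Among unnamed probes probe_2373 was 1.66-fold higher (0.73 ± 0.05). probe_4433 was well above background in the reference on 5 of 8 arrays and in the cultures on none, at least 2.29-fold lower with limma adjusted p of 0.0354, and the annotation used here gives it no name. The count was 0 without high-oxygen light replicate 2 and 0 without low-oxygen light replicate 2. It was 3 without high-oxygen light replicate 1, 28 without high-oxygen dark replicate 2 and 124 without low-oxygen dark replicate 1.

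The size of each effect was compared through its spread over all probes. The standard deviation was 0.171 for oxygen, 0.183 for light and 0.160 for the interaction contrast, which holds interaction and culture spread together. Correlations across probes between dye orientations, in which probes are not independent replicates, were 0.0097 for oxygen, 0.0956 for light and -0.0165 for interaction. In the brightest 538 probes they were 0.334, 0.287 and 0.243, and the standard deviations were 0.114, 0.0821 and 0.0824. Oxygen, not light, thus had the largest spread there, and light had no more than the interaction contrast. For the cultures against the reference r was -0.0428 over all probes, -0.407 in the dimmest 538 and 0.471 in the brightest 538. A fit to the 8 arrays as if they were replicates, whose spread is technical, gave 0 probes for the interaction in limma, with 125 at an unadjusted p under 0.05 with the dye orientation as a replicate block and 39 without it, against 134.4 by chance. In the fit with that block the dye term passed for 354 probes.

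**Figure D3:**
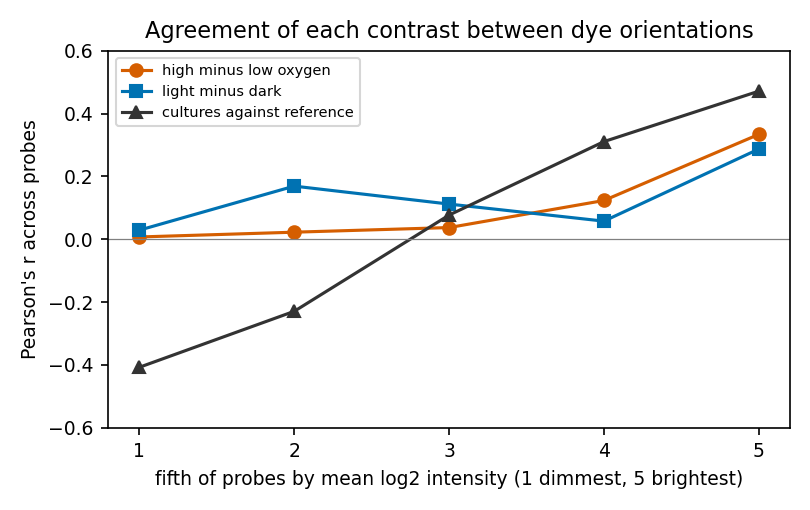
Pearson's r across probes between the arrays with the culture in Alexa 532 and those with it in Alexa 647 (y axis) in groups of 537 or 538 probes ordered by mean log2 intensity from dimmest to brightest (x axis), with lines for the oxygen, light and reference comparisons. In the brightest group r was 0.334 for oxygen, 0.287 for light and 0.471 against the reference, and the reference comparison started from -0.407 in the dimmest.

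The lists drawn up later also held 0 past the test in any comparison. Their counts include members not well above background on any array, such as hutU of histidine degradation. For oxygen the lowest adjusted p was 0.578, and the members with higher values at high oxygen were 5 of 12 for aminoacyl-tRNA synthetases, 2 of 11 for amino acid synthesis, 2 of 6 for histidine synthesis, 1 of 3 for histidine degradation, 4 of 7 for purine synthesis, 7 of 10 for carbon metabolism and 11 of 16 for cofactor synthesis. With the authors' values carbon metabolism held 1 of 10 higher at high oxygen, amino acid synthesis 5 of 11 and cofactor synthesis 8 of 16, and with median centring carbon metabolism held 3 of 10 and purine synthesis 3 of 7. For light, 6 of 7 purine synthesis genes were higher, with purF and guaB as above and a list adjusted p of 0.189, and an adjusted p of 0.773 with an estimated correlation. Under the other scalings 5 to 7 of these 7 genes were higher. Against the reference 8 of 10 carbon metabolism genes were lower (6 of 10 from the high scan alone), with mdh at -0.22 ± 0.05 and a list adjusted p of 0.265.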

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

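The high scan alone and the test on 525 bright probes were chosen after the data were seen, the others were planned. For the count against the reference (235), it was 783 without background correction, 632 with median centring, 378 with print-tip loess, 503 without the dimmest 25% of probes, 422 with the median of spots, 767 with the robust and trended prior and 558 with the authors' values. It was 328 from the arrays with the culture in Alexa 532 alone and 0 from those with it in Alexa 647. Fits of 8 arrays gave 835 with a dye term and the culture as a random block, 473 with the dye orientation as a replicate block and 152 with no replicate block. Leaving out 1 array gave 0 to 223. For oxygen (0) the count was 2 without background correction, 29 with median centring, 29 with the robust and trended prior, 1 with the random block, 37 with the authors' values and 2 among bright probes. For light (0) it was 107 with median centring and 26 with the authors' values. Both were 0 under every other setting, including each left-out array and both replicate-block fits. No list of the 7 set in advance passed for oxygen or light under any alternative run for lists. The contrasts' standard deviations for oxygen, light and interaction were 0.0986, 0.112 and 0.0922 without background correction and 0.259, 0.275 and 0.245 from Alexa 647 alone. The cause of these changes was not tested, except that one orientation alone uses 4 of the 8 arrays.

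The 11 named genes past the threshold against the reference kept their sign in the 22 settings of processing and left-out arrays (21 for purB). arcC kept its call in 17 of 22 (log2 0.41 to 0.49), rpl12p in 18 (-1.01 to -0.46), rpmC in 17 (-0.58 to -0.44) and carB in 16 (-0.38 to -0.23). Calls were kept in 15 for sucC (-0.37 to -0.25), argH (0.17 to 0.64), gyrA (-0.40 to -0.26) and thiL. They were kept in 14 for hemA (-0.65 to -0.12), in 13 for cbiT (-0.42 to -0.14) and in 11 of 21 for purB. For oxygen 71 of 968 values of genes named by the rule or in lists changed sign under processing settings, and 102 of 840 with an array or culture left out. For light these were 65 of 977 and 125 of 852. Spots flagged in the tables and a block for scan date were not run, since neither is in the tables used here. A block for slide was not run either, since each array has its own number and the numbers follow oxygen. Arrays sharing a replicate number share only the dye orientation. Signal over background leaves 1269 of 2688 probes, not well above background in the cultures on any array, without a measured level there, and leaving an array out leaves its culture with 1 dye orientation and an uncancelled dye bias.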

Other observations

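The refits on bright probes, the comparison of correlations by brightness, the trended-prior probes, the pairing and exchange of arrays, the correlation between orientations among bright probes, and the neighbour tests on measured pairs and by resampled pairs were chosen after the result they bear on had been seen. The neighbour tests on all pairs, their print position check and the shuffles over all probes were fixed before their results were seen.

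Among the 52 named genes well above background on all 8 arrays, 26 passed against the reference when these bright probes were tested alone, 13 higher and 13 lower. So did 334 of all 525 bright probes, 184 higher and 150 lower, of which 275 had the same sign in both orientations. The 525 were chosen by the culture's dye alone, a side of the ratio tested, which can favour probes higher in the cultures. Signal well above background in the reference's dye was not required. On high-oxygen light replicate 2, 19.9% of all probes met the criterion in the culture's dye and 13.2% in the reference's. Shuffling an orientation's values among the 525 bright probes gave a median of 340 calls over 100 shuffles, so the count alone does not set these probes apart. Such shuffles leave uncancelled the dye bias that the real means cancel. Their calls with the same sign numbered 226 in the median and 259 at most. Higher in the cultures were arcC, argH and arcA (0.25 ± 0.02), both aspartate carbamoyltransferase genes, pyrB (0.11 ± 0.02) and pyrI (0.15 ± 0.03), the ferritin-like gene dpsA (0.22 ± 0.02), gdhB (0.20 ± 0.02), purE (0.10 ± 0.03) and psmA (0.08 ± 0.02, higher on 4 of 8 arrays, and -0.03 with print-tip loess over all probes). All 4 bright chemotaxis genes were also higher, cheY (0.18 ± 0.02), cheB (0.17 ± 0.02), cheA (0.16 ± 0.02) and cheR (0.08 ± 0.02). Lower were rpl12p, rpmC, hemA, sucC, sucD (-0.14 ± 0.03), the malate dehydrogenase gene mdh (-0.22 ± 0.03), the enolase gene eno (-0.17 ± 0.03) and sdhC (-0.10 ± 0.02). The phosphate regulator gene phoU (-0.24 ± 0.03, lower on 6 of 8 arrays), cbiT, cbiG (-0.25 ± 0.03), the agmatinase gene speB (-0.27 ± 0.02) and the protein export gene secY (-0.15 ± 0.02) were also lower. All 7 bright carbon metabolism genes had values below 0 and 4 of them passed. As lists, chemotaxis and carbon metabolism both had an adjusted p of 0.338 over 9 lists.

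In light, the purine synthesis list had an adjusted p of 0.0325 among bright probes, with 4 of 5 members higher in light and a median of 0.14, although no member passed alone. With an estimated correlation the adjusted p was 0.892 among bright probes. Over all probes it was 0.189, and 0.773 with an estimated correlation, and the list was drawn up after the gene names were known.

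For oxygen, the robust and trended prior called 29 probes, none with a gene name, of which 25 were well above background on all 8 arrays. Their changes ran from 0.19 to 0.96 in size on the log2 scale. That prior held 41.7 degrees of freedom, against 1 from the cultures, so its p-values lean on the trend.

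The oxygen and light contrasts over all probes hardly repeated between dye orientations, with r of 0.0097 and 0.0956. A high-oxygen array assigned to the wrong culture in only its own orientation was argued against. Among the 24 ways to pair the arrays of the 2 orientations over the brightest 538 probes, the labelled pairing had a sum of correlations of 1.18. This was higher by 0.768 (bootstrap 95% interval over probes 0.313 to 0.972) than any that moves a high-oxygen array. A culture exchanged with another on both of its arrays would keep this pairing as the best, so that case could not be tested. Exchanging the low-oxygen arrays of one orientation leaves its oxygen contrast as it is, and for light this stays open: the labelled pairing exceeded it by 0.0389 (-0.107 to 0.183), and exchanging changed r for light by -0.0565 (-0.110 to 0.00016). Signal near background is a candidate explanation for oxygen, since its correlation was higher in the brightest 538 than in other probes by 0.346 (bootstrap 95% interval 0.189 to 0.489). For light the difference was 0.198 (0.0643 to 0.323), but agreement did not rise steadily with brightness. The correlation of ranks for light was 0.211 in the second-dimmest 537 probes and 0.180 in the brightest 538. Signs matched in 60.1% and 53.0% of these, so for light this explanation stays open. Small true responses to oxygen and light stay open too, untested.

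A dye bias of a probe that is the same on both arrays of a culture cancels in the culture's mean, so it does not account for the 235 probes differing from the reference, while bias or noise that differs between arrays stays open. Shuffling one orientation among probes of like brightness gave as many same-sign calls as the real 217 in 32 of 100 shuffles. It leaves uncancelled the bias that the real means cancel, so it decides nothing, although it had been set beforehand as the test. Among the 525 bright probes noise that differs between orientations was argued against as the whole source, since the orientations correlated with r = 0.480 (bootstrap 95% interval 0.410 to 0.542). Strain, medium and growth conditions remain open, since the design has 1 reference RNA.

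A hypothesis was that genes lying next to each other share their differences, as genes of one transcription unit would, in the gene order of strain 91-R6, which may differ from that of NRC-1. Against the reference the 20 adjacent pairs of named genes, such as arcC and arcA (0.45 and 0.25), cheB and cheY (0.17 and 0.18) and gyrB and gyrA (-0.29 and -0.35), had a mean absolute difference of 0.124 (bootstrap 95% interval 0.0717 to 0.195), against 0.212 in shuffles (one-sided permutation p = 0.00081, adjusted 0.00243 over 3 tests), and 14 of 20 had 1 sign. In the 13 pairs with both genes well above background on at least 1 array in culture and reference, the permutation p was 0.00012 and 12 had 1 sign, and printing side by side was argued against, since 1 pair of the 20 shared a print block and the permutation p was 0.00067 with print-tip loess. Of the pairs, carB and carA (-0.32 and 0.02) differed, and gatC and gatA most (0.52 and -0.12), with gatC not well above background on any array. Neighbours were taken by gene order alone, without their strand or distance. With these limits, the smaller differences are what shared transcription units would give. For oxygen (permutation p of 0.138) and light (0.481) the values lay within the shuffles, set beforehand as counting against it, but the intervals of the mean differences, 0.0646 to 0.168 and 0.0787 to 0.198, reached below 0.102 and 0.108, the values under which 5% of shuffles lay, so it stays open.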
